A study of Homo sapiens with 36 samples.

How the data were processed

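RNA from MDA-MB-231 D3H1 Luci cells in culture and from xenografts was measured with the nCounter human stem cell panel in 36 lanes, 1 per sample, per the labels. The table holds 213 targets: 193 genes, 6 housekeeping genes (CLTC, GAPDH, GUSB, HPRT1, PGK1 and TUBB), 6 positive controls and 8 negative controls. The deposited values are nCounter signal, which the authors processed with nSolver 2.070, per the submitters' processing notes; these do not state the normalization. From the values, gene signal equals a lane factor times a background-subtracted count with a floor of 1, and the factor brings the geometric mean of the positive controls to 1 value in all lanes. All 2592 of 2592 gene values below 200 lay on the step grid this predicts (tolerance 0.05 steps), and 312 of 312 control values shared the lane's fraction (tolerance 0.011). Nothing in the values scales lanes to the housekeeping genes or RNA input, so signal also depends on the amount of RNA in a lane. The whole-number part of each background is unknown, so raw counts were not recovered and no count test was run. The number of lanes limits the precision.

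Lanes were grouped by treatment and setting as the labels give them. Initiation saline replicate 2 had all positive controls at 1 and a single value of 571 in every gene, and was left out of every fit. This departs from the design fixed before the data were examined; the closing section gives the counts with it kept. A ratio of the 2 highest positive controls under 2.2 placed 12 lanes in set 1 (1.87 to 2.10) and a ratio above it 23 in set 2 (2.32 to 2.74). The sets were inferred from the values, not given by the labels; a cartridge holds 12 lanes. Of the gene symbols, 195 are current, 2 older (T is TBXT and MAP3K7IP1 is TAB1) and 2 were not matched in the reference names. The closest pair of lanes had a Pearson r of 0.995 across genes, with 0 equal genes.

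Tests used log2 of the signal plus 1 in limma 3.58.1 under R 4.3.3 (lmFit, contrasts, eBayes without trend), with Benjamini-Hochberg adjustment over 193 genes and a threshold of 0.05; control probes and housekeeping genes were not tested. The SFN and stage comparisons of tumours shared 1 fit of the 31 tumours with signal, culture SFN was fitted on its 4 lanes, and tumours were compared with culture in a fit of all 35 lanes. Adjusted p-values in the text come from limma unless named otherwise. The series' rule (unadjusted p under 0.05 and 1.5-fold) and an unequal-variance test per gene were run beside it. Of 19 lists fixed in advance, 16 had at least 3 measured members and were tested with fry and with camera (preset correlation 0.01, and estimated). fry tests whether a list's genes move one way on balance, and does not compare them with other genes. The negative-control floor was the mean plus 2 SD of the negative controls, 4.99; where the mean or at least 50% of the lanes of 1 group lay under it, the fold is given as a bound, the mean of the other group over the floor or, if larger, over the lower mean. Control values carry no lane factor, while that of the genes ran from 0.674 to 1.46 in lanes with signal. The floor is thus not on the scale of the genes, and these bounds are approximate. Tumours on a side were counted on log2 signal. Single lane measures were compared by two-sided permutation, exact within sets and with 1e+05 resamples over both. Random lists, 10000 per test, drew each member from the 20 genes nearest in level. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

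Named genes followed a rule fixed in advance: the 10 largest rises and 10 largest falls among genes passing, or the 10 smallest p-values where fewer than 10 passed; for SFN also the stem-cell genes recalled from the study's publication and CD44, MYC, CCND1, NOTCH1, JAG1, CTNNB1 and CDH1; and up to 4 members of a called list. Not all are printed.

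The tests were tried on simulated data, 20 sets per comparison with 40 of 193 genes changed. Noise was drawn independently for each gene and lane. In the data, genes under 32 in culture moved together (mean pairwise correlation 0.634 within growth groups). The recovered and false shares below may therefore not hold for the real lanes. At a log2 change of 1 the growth comparison recovered 43.5% and at 2 it recovered 88%, with 5.05% of calls false. The initiation comparison recovered 23% and 64.5%, the culture comparison 65.3% and 86.8%, the stage comparison 31.8% and 73.3%, and the stage difference of the SFN effect 13.8% and 48.5%. Growth against culture recovered 12% and 39%, and initiation against culture 7% and 36.8%. A shifted list was called in 20 of 20 simulations for growth, 19 for initiation and 15 for culture. Alternatives covered scaling, pseudocount, filter, variance model, array weights, groups fitted, threshold, test, replicate block, left-out lanes, weak lanes and lane sets.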

Results

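Expression of 193 stem-cell and developmental signalling genes was measured with human probes on the NanoString nCounter, an assay that counts colour-coded probes hybridised to RNA without amplification. The cells were the D3H1 Luci derivative of MDA-MB-231 (spelled MDA-MD-231 in the culture sample titles), an established human triple-negative breast cancer line that carries luciferase. Sulforaphane (SFN), an isothiocyanate formed from broccoli glucosinolates, was compared with saline in 3 settings. Cells in monolayer culture received 7.5 µM SFN or saline for 48 hours, with 2 lanes per group. Xenografts grown from 50000 cells in Balb/c nude mice came from animals given daily injections of SFN at 50 mg/kg or of 0.9% saline; the labels give a schedule for SFN, from 2 weeks before inoculation to 3 weeks after it. Growth tumours, removed on day 35 per the sample labels (the growth protocol gives 30 days), numbered 10 per treatment. Either day lies after the stated 3 weeks of SFN. Initiation tumours, removed before day 20 and so before the stated 3 weeks had passed, numbered 6 per treatment, and 1 of the 6 saline lanes held no signal.

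The summed signal of a lane ranged from 579380 to 667511 in culture, from 123014 to 701132 in growth tumours and from 65400 to 583464 in the initiation tumours with signal. The geometric mean of 6 housekeeping genes was 8718 ± 2591 (SD, n = 10) in growth saline tumours and 7725 ± 2343 (SD, n = 10) in growth SFN tumours. It was 9466 ± 1771 (SD, n = 5) in initiation saline and 9480 ± 4278 (SD, n = 6) in initiation SFN tumours, where replicate 3 lay at 768. In culture, 53 genes had a mean signal under 32; they are called low-level genes here. Their median signal was 7.06 ± 1.12 (SD, n = 2) in culture saline, 9.53 ± 1.86 (SD, n = 5) in initiation saline and 73.9 ± 31.0 (SD, n = 10) in growth saline, against 45.4 ± 15.8 (SD, n = 10) in growth SFN. Negative controls reached at most 8.34. The positive controls divided the lanes into a set of 12 (culture replicate 1 of each treatment and growth replicates 1 to 5) and a set of 23 (the other culture and growth lanes and all initiation lanes with signal).

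**Figure D1:**
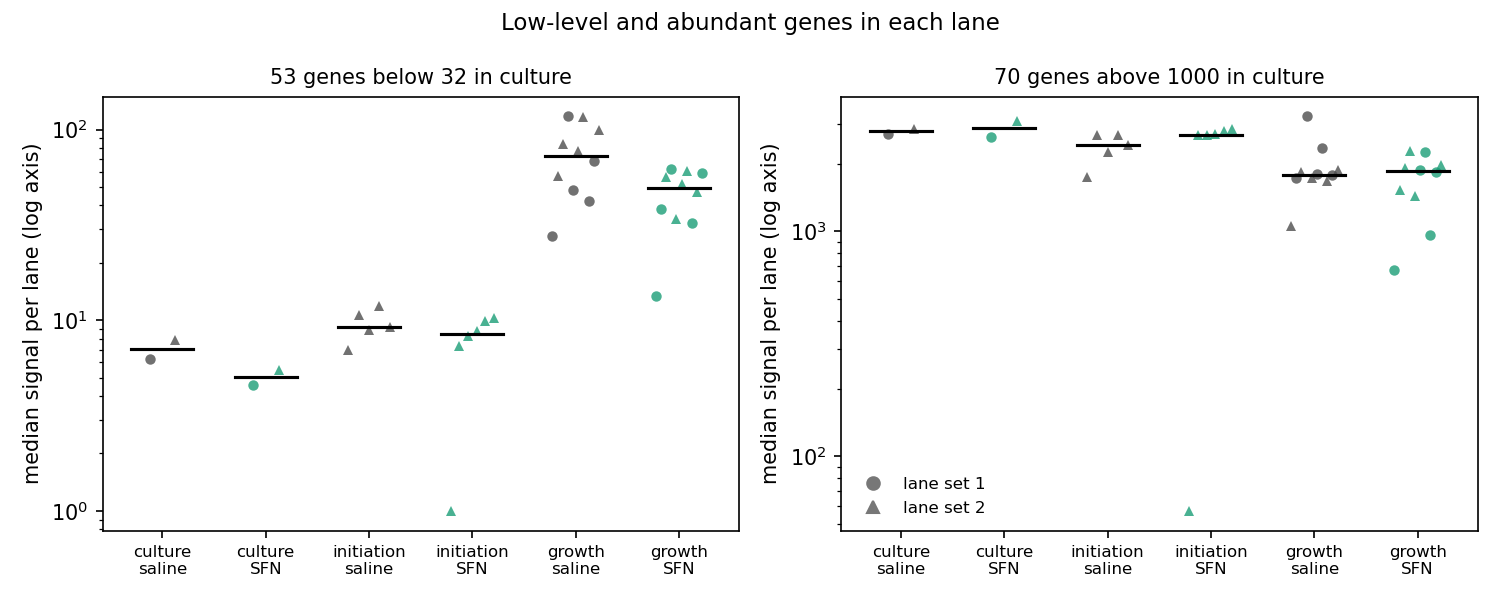
Median signal per lane on a log axis, by group, for the 53 low-level genes and for the 70 genes above 1000 in culture (abundant genes). Circles are lanes of set 1, triangles lanes of set 2, and lines are group medians. The low-level genes sat at 73.9 on average in growth saline tumours and at 9.53 in initiation saline tumours. In the abundant genes initiation SFN replicate 3 lay at 57.3, far below the other lanes of its group (2674 to 2868).

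The first comparison asked whether SFN altered stem-cell and signalling genes in growth tumours, the question the series text poses. Genes tied to an undifferentiated state had lower mean signals with SFN, but none passed the test over all genes. GDF3, a TGF-beta family ligand of pluripotent cells, had a mean signal of 84.8 ± 36.9 (SD, n = 10) with saline and 36.7 ± 16.2 (SD, n = 10) with SFN. NANOG, a core pluripotency transcription factor, had means of 568 ± 243 and 286 ± 108, and ALDH1A1, an aldehyde dehydrogenase used as a marker of breast cancer stem cells, 94.3 ± 33.3 and 52.7 ± 21.3. FOXD3, a transcription factor of embryonic stem cells and neural crest, had means of 95.1 and 43.5, and the ligand gene WNT3 had 256 and 168. All 10 SFN tumours lay below the saline mean for each of these 5 genes.

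By limma, 0 of 193 genes passed an adjusted p of 0.05; 28 had an unadjusted p under 0.05, all lower with SFN. An unequal-variance test per gene also gave 0 after adjustment, and 32 genes by the series' own rule of unadjusted p and 1.5-fold. The smallest limma values belonged to GDF3 (log2 fold change −1.26 ± 0.35 SE, adjusted p = 0.108), ISL1, a LIM homeobox factor of motor neurons and pancreas (−0.97 ± 0.28, 0.108), and COL2A1, the cartilage collagen (−1.29 ± 0.38, 0.108). Each lay below the saline mean in 10 of 10 SFN tumours, as did PDX1, a pancreatic transcription factor (means of 57.7 and 28.2), GAS1, a hedgehog co-receptor (−1.13 ± 0.36), and S100B, a glial calcium-binding protein (−1.09 ± 0.35). FZD10, a Wnt receptor, had −1.10 ± 0.34, with a mean signal of 43.9 with saline. Its highest SFN value, 39.3, lay above the saline mean on log2 signal, so FZD10 is not among these genes. The gap-junction gene GJB1 (−0.99 ± 0.33) and the T-cell co-receptor gene CD8B (−0.97 ± 0.33) both had an adjusted p of 0.124. For NANOG the change was −0.96 ± 0.38 (adjusted p = 0.245), for ALDH1A1 −0.86 ± 0.35 (0.248), for FOXD3 −1.09 ± 0.39 (0.172), for WNT3 −0.63 ± 0.55 (0.716) and for the receptor gene NOTCH4 −0.42 ± 0.62 (0.716, below in 9 of 10). The cell-surface receptor gene CD44 had −0.25 and the transcription factor gene MYC −0.10.

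The call depended on lanes outside the comparison: a fit of only both groups called 3 genes lower, and without initiation SFN replicate 3, 22 genes were lower, among them GDF3 (adjusted p = 0.023), NANOG (0.022), ALDH1A1 (0.024), FOXD3 (0.015) and WNT3 (0.024). Without it but scaled to the housekeeping genes, 0 genes passed, with a low-level median of −0.52 and an abundant median of −0.09; set 1 alone gave 0 genes, set 2 alone 47, and the set of lanes as a covariate 19.

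**Figure D2:**
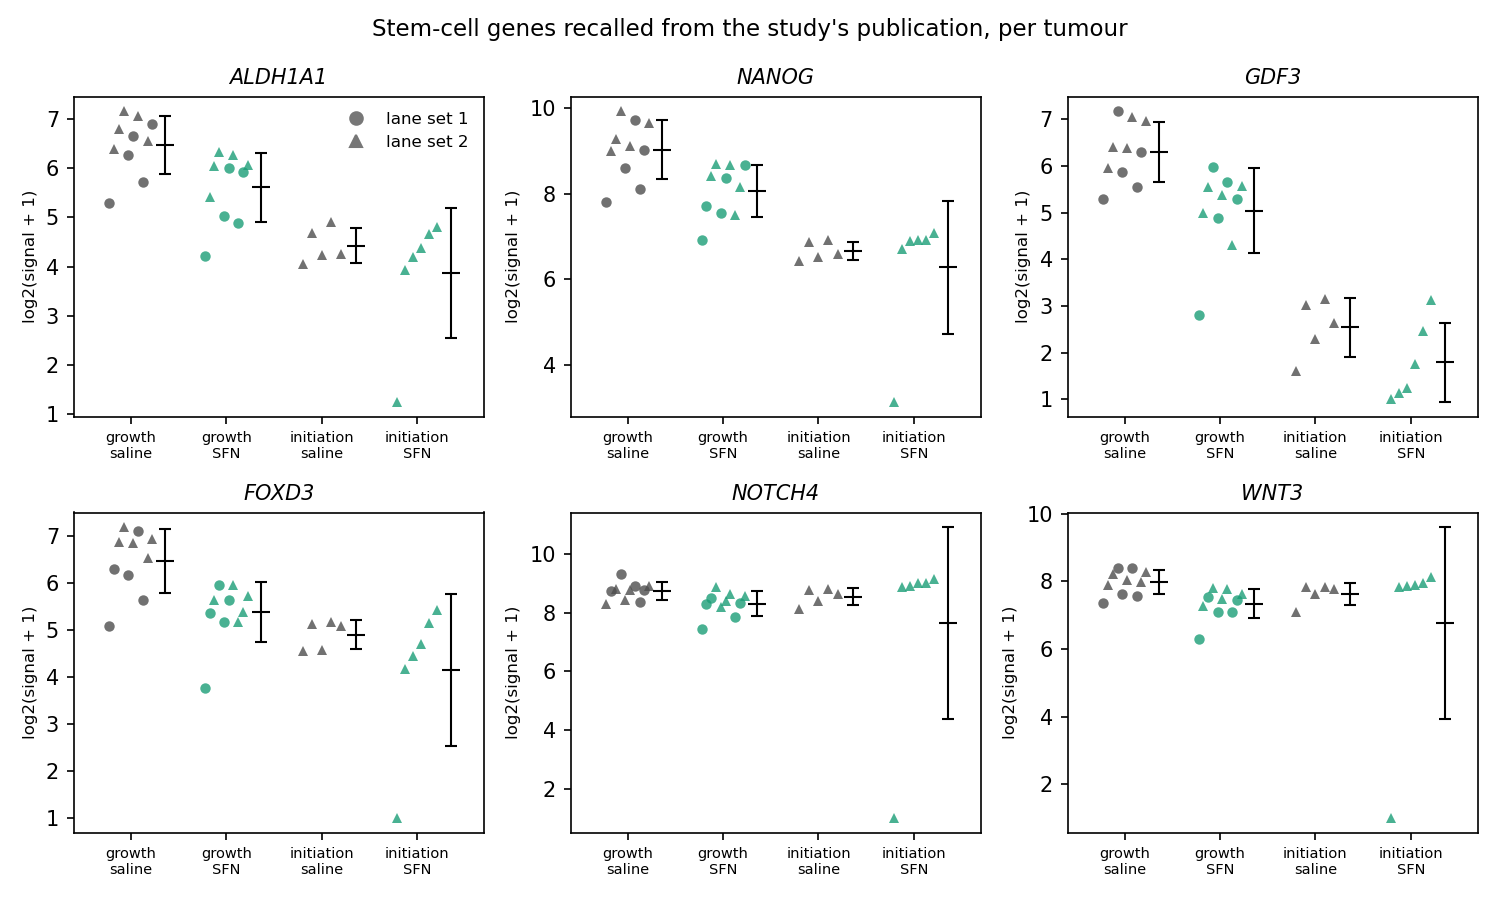
Log2 of signal plus 1 for the stem-cell genes recalled from the study's publication, per tumour lane, in growth and initiation tumours with saline or SFN. Circles are lanes of set 1, triangles lanes of set 2, and black bars mean ± SD on that log2 scale. Unlogged NANOG signal averaged 568 with saline and 286 with SFN in growth tumours, and 101 in both initiation groups. Initiation SFN replicate 3 read 7.78 for NANOG, and the other lanes of its group 103 to 135.

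Most genes leaned the same way: 49 of the 53 low-level genes had a lower value with SFN, with a median log2 difference of −0.72, against −0.29 for the 70 genes above 1000 in culture. Without growth SFN replicate 1, the lane with the lowest summed signal among growth tumours, the low-level median was again −0.72 and the abundant median −0.10. The lane mean of the low-level genes differed by −0.64 (permutation p = 0.0380, adjusted p = 0.152 over 4 measures), that of the abundant genes by −0.27 (permutation p = 0.283, adjusted p = 0.380). Within set 1 the low-level difference was −0.51 (exact permutation p = 0.325, adjusted p = 0.434 over 8 tests within sets) and within set 2 −0.77 (exact permutation p = 0.0159, adjusted p = 0.0952). The abundant genes differed by −0.71 within set 1 (exact permutation p = 0.119, adjusted p = 0.254), more than the low-level genes, and by +0.17 within set 2 (exact permutation p = 0.468, adjusted p = 0.535). These tests were two-sided.

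No gene list passed in growth tumours: limma's fry called 0 of 16 lists, 7 had an unadjusted p under 0.05, and camera with a preset correlation called 6 as lower and 0 with an estimated one (lowest adjusted p = 0.533). Of the 6 measured genes recalled as named by the study, 0 passed over all genes and 4 were lower when adjusted over the list alone. The list's median was −0.91 (fry adjusted p = 0.109). That list was recalled from the study's publication and is taken to have been chosen on these samples, so its count is not independent evidence. Among 9 pluripotency and germ-cell genes 3 were lower adjusted over the list alone (median −0.68, adjusted p = 0.109). Markers of other lineages and cells had values as low. The 6 mesoderm and endoderm genes had a median of −0.90, the 4 lymphoid and myeloid markers −0.88, the 6 stroma, bone, cartilage and fat markers −0.80 and the 5 neural genes −0.77, each with a fry adjusted p of 0.109; adjusted over the list alone, 3, 2, 2 and 2 genes were lower. The 5 TGF-beta and BMP genes had −0.37 (adjusted p = 0.109, 1 gene adjusted over the list alone) and the 3 keratin and epithelial genes −0.25 (0.221, 1 gene). Medians were −0.61 for 7 stem-cell markers (fry adjusted p = 0.289) and −0.49 for 11 hedgehog genes (0.289, 1 gene adjusted over the list alone). They were −0.42 for 44 Wnt genes (0.339) and −0.26 for 4 FGF genes (0.322). The rest were −0.38 for 9 cell-cycle genes, −0.31 for 38 Notch genes and −0.28 for 8 chromatin regulators (0.513 each). For 8 adhesion genes the median was −0.26 (0.508, 1 gene adjusted over the list alone). Without initiation SFN replicate 3, or with the set of lanes as a covariate, 11 lists were lower; scaled to the housekeeping genes, 0 (median of the study's list −0.71).

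In initiation tumours the question was whether SFN acted before tumours were established. The pluripotency gene NANOG had a mean signal of 101 ± 15.3 (SD, n = 5) with saline and 101 ± 46.6 (SD, n = 6) with SFN, and ALDH1A1 21.1 ± 5.61 and 17.3 ± 9.05. NOTCH1, a receptor of the Notch pathway, had means of 245 ± 45.3 and 157 ± 79.4, and FOSL1, an AP-1 subunit, 5945 ± 638 and 4006 ± 2000. TERT, the catalytic subunit of telomerase, had means of 59.7 and 36.0.

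limma called 0 of 193 genes, and the unequal-variance test 0 after adjustment and 1 by the series' rule; 3 genes had an unadjusted p under 0.05 in limma, each with an adjusted p of 0.543. They were MAP3K7IP1, the TAK1-binding adaptor now named TAB1 (−0.60 ± 0.27 SE), TERT (−1.22 ± 0.58) and NOTCH1 (−1.42 ± 0.69), each below the saline mean in 6 of 6 tumours. FOSL1 had −1.48 ± 0.77, also below in 6 of 6, and the casein kinase gene CSNK1G3 +0.43 ± 0.24, above in 6 of 6. The pluripotency factor gene SOX2 had −0.85 ± 0.42. No list passed: fry called 0 of 16, 0 had an unadjusted p under 0.05, camera called 0 with either correlation, and the lowest adjusted p was 0.474. Medians ran from −0.83 for the cell-cycle list to −0.11 for the mesoderm and endoderm list; without replicate 3 of the SFN group they were +0.18 and +0.19, the Notch list went from −0.75 to +0.20 and the Wnt list from −0.61 to +0.14. The values rested on replicate 3 of the SFN group: without it NOTCH1 had −0.37 and FOSL1 −0.31, NANOG had +0.24 in place of −0.39, and limma again called 0 genes.

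The SFN effect was then compared between the stages. By the stated schedule, growth tumours were removed after SFN dosing had ended and initiation tumours before its end. Stage and time since the last dose therefore cannot be told apart. limma found 0 of 193 genes whose SFN effect differed, and 2 with an unadjusted p under 0.05. These were ISL1 (difference of log2 fold changes −1.32 ± 0.48 SE, adjusted p = 0.962) and S100B (adjusted p = 0.962; under the negative-control floor of 4.99 in initiation saline), whose mean signals were lower with SFN in growth tumours (147 and 69.7 for ISL1, 49.5 and 21.6 for S100B) and not in initiation tumours (19.9 and 25.7, 3.30 and 5.67). NANOG gave −0.57 ± 0.64 SE (adjusted p = 0.993) and ALDH1A1 −0.30 ± 0.59 (0.993). These values rested on initiation SFN replicate 3: without it NANOG gave −1.20 ± 0.42 (adjusted p = 0.190) and ALDH1A1 −0.83 ± 0.43 (0.289), and the median of the study's list went from −0.32 to −0.89. limma then again called 0 genes, with 30 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0880, and the median of all genes went from +0.23 to −0.54 (−0.07 when also scaled to the housekeeping genes).

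In culture the comparison asked what SFN did to the cells without a host. CDK1, the kinase that drives entry into mitosis, had a mean signal of 10227 ± 239 (SD, n = 2) with saline and 17780 ± 1935 (SD, n = 2) with SFN. CCNA2, the cyclin A2 of S phase and G2, had 7392 ± 194 and 11014 ± 259, and ABCG2, a drug-efflux transporter of stem-like cells, 34.0 ± 1.91 and 57.9 ± 4.75. The ALDH1A1 signal was 9.24 and 7.14, and that of NANOG 35.0 and 33.0.

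limma called 0 of 193 genes, and the unequal-variance test 0 after adjustment and 5 by the series' rule; 17 had an unadjusted p under 0.05 in limma. CDK1 had a log2 fold change of +0.79 ± 0.16 SE (adjusted p = 0.311), ABCG2 +0.75 ± 0.16 (0.311) and CCNA2 +0.58 ± 0.14 (0.465), each above both saline lanes in 2 of 2 SFN lanes. Housekeeping signal was also higher with SFN (mean 12973 against 10879). Scaled to it, CDK1 had +0.54, ABCG2 +0.50 and CCNA2 +0.32, and 0 genes passed. The smallest adjusted p was 0.206, for COL2A1 (means of 10.2 and 1.38, at least 2.05-fold lower against the negative-control floor of 4.99) and the ligand gene WNT1 (means of 3.89 and 1.12, both under that floor). SMO, the hedgehog signal transducer, had means of 8.03 and 3.98, at least 1.61-fold lower. These 3 lay below both saline lanes in 2 of 2 SFN lanes. The set of lanes as a covariate gave 14 genes with 1 residual degree of freedom left. fry called 0 of 16 lists, 0 had an unadjusted p under 0.05 and the lowest adjusted p was 0.854 (stem-cell markers, median +0.22); camera called 0 with either correlation. Scaled to the housekeeping genes, 5 lists were lower, as that scaling moved the medians down: the Notch list from −0.07 to −0.32 and the chromatin regulators from −0.01 to −0.26.

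Initiation saline tumours were set against cultured saline cells to show what differs in early tumours. The positive-control ratio was 1.96 and 2.35 in the 2 culture saline lanes and 2.45 to 2.74 in the initiation saline lanes. Tissue and a possible difference of assay run therefore cannot be told apart in this comparison. Signal rose in tumours for PRKD1, protein kinase D1 (mean 154 ± 48.9, n = 5, against 6.62 ± 7.94, n = 2), and for FGF2, the basic fibroblast growth factor used to maintain stem cells (120 ± 23.5 against 3.86 ± 3.39). SMO rose from 8.03 ± 0.247 to 200 ± 37.4 and NOTCH3, a Notch receptor, from 59.1 ± 6.06 to 486 ± 85.2. MYC fell from 15404 ± 239 in culture to 4668 ± 404. Each of these changes was seen in 5 of 5 tumours, all beyond both culture lanes.

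limma called 11 genes higher and 2 lower of 193. The log2 fold changes were +4.45 ± 0.39 SE for SMO (adjusted p = 1.57e-10) and +3.00 ± 0.43 for NOTCH3 (2.28e-06). FGF2 and PRKD1, each under the negative-control floor in 1 of the 2 culture lanes, were at least 24.1-fold (2.37e-09) and 23.3-fold higher (1.69e-09). SFRP4, a secreted Wnt antagonist, had +3.64 ± 0.70 (0.000436) and COL1A1, the main collagen of connective tissue, +3.56 ± 1.00 (0.023; 661 against 54.7). Also higher were PRKCB (+2.67), N-cadherin CDH2 (+1.86), the Wnt ligand WNT11 (+1.48) and MAP3K7IP1 (+1.46). The 11th gene, the kinase NLK (+1.03), falls outside the naming rule and was named after its values were seen. MYC had −1.73 ± 0.40 (adjusted p = 0.00384) and COL2A1, at 10.2 in culture and 1.01 in tumours, was at least 2.05-fold lower (0.023). All 13 genes lay beyond both culture lanes in 5 of 5 tumours. PRKD1, SMO, PRKCB, CDH2 and WNT11 also read higher in initiation SFN replicate 3, the lane with the least housekeeping signal, than in any other initiation SFN lane. Growth SFN replicates 1 and 2, with the least housekeeping signal of their group, read highest in it for PRKCB and CDH2. PRKD1 and WNT11 were highest in replicate 1 but not high in replicate 2, and SMO was highest in replicates 8 and 9. Growth saline replicate 6, with the least housekeeping signal of the growth saline lanes, did not read highest for PRKCB or CDH2. fry called no list (lowest adjusted p = 0.0734, for the 4 FGF genes). Scaled to the housekeeping genes, the FGF list (fry adjusted p = 0.00174) and the hedgehog list (0.0184) passed as higher. Both also passed without initiation SFN replicate 3 (fry adjusted p = 0.00423 and 0.0114). Without culture saline replicate 1 the count fell to 5, and scaled to the housekeeping genes it was 30 (21 higher, 9 lower).

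Growth saline tumours differed from cultured saline cells in many more genes. SMO, at 8.03 in culture, had a mean signal of 354 ± 141 (SD, n = 10), and NANOG, at 35.0, had 568 ± 243. FGF2 rose to 84.9 ± 24.2 and PRKD1 to 110 ± 27.0. GDF3, at 1.50 ± 0.707 in culture, had 84.8, and the T-cell gene CD8B, at 1.92 ± 0.651, had 144. MYC fell to 3540 ± 906, and PPARG, the nuclear receptor of fat cell formation, from 1299 ± 157 to 401 ± 93.8.

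limma called 56 genes higher and 4 lower of 193, and 47 of them were low-level genes in culture. The changes were +5.20 ± 0.37 SE for SMO (adjusted p = 2.86e-13) and +3.85 ± 0.63 for NANOG (8.38e-06). Against the floor of 4.99, which their culture means did not reach, CD8B was at least 28.9-fold higher (2e-09), the growth factor gene IGF1 at least 28.7-fold (1.09e-07) and GDF3 at least 17.0-fold (4.22e-08). The lower genes included MYC (−2.16 ± 0.37, 1.08e-05), PPARG (−1.72 ± 0.45, 0.00201) and the kinase PRKCE (−0.70 ± 0.26, 0.0402). MYC and PPARG lay below both culture lanes in 10 of 10 tumours and PRKCE in 9 of 10; the 5 higher genes lay above both in 10 of 10. fry called 10 of 16 lists. Among them, 7 of 9 pluripotency genes rose and 1 fell (fry adjusted p = 0.00043), 4 of 4 lymphoid and myeloid markers rose (3.87e-07), as did 5 of 6 mesoderm and endoderm genes (9.18e-05), 5 of 6 stroma markers with 1 lower (0.000187), 2 of 4 FGF genes (0.000172) and 4 of 11 hedgehog genes (0.00725). None of these 6 held with an estimated correlation (adjusted p = 0.714 for each of the 6). Among the genes at 32 or more in culture, 5 of 140 passed (3 higher, 2 lower), and scaled to the housekeeping genes the count was 93 (79 higher, 14 lower).

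**Figure D3:**
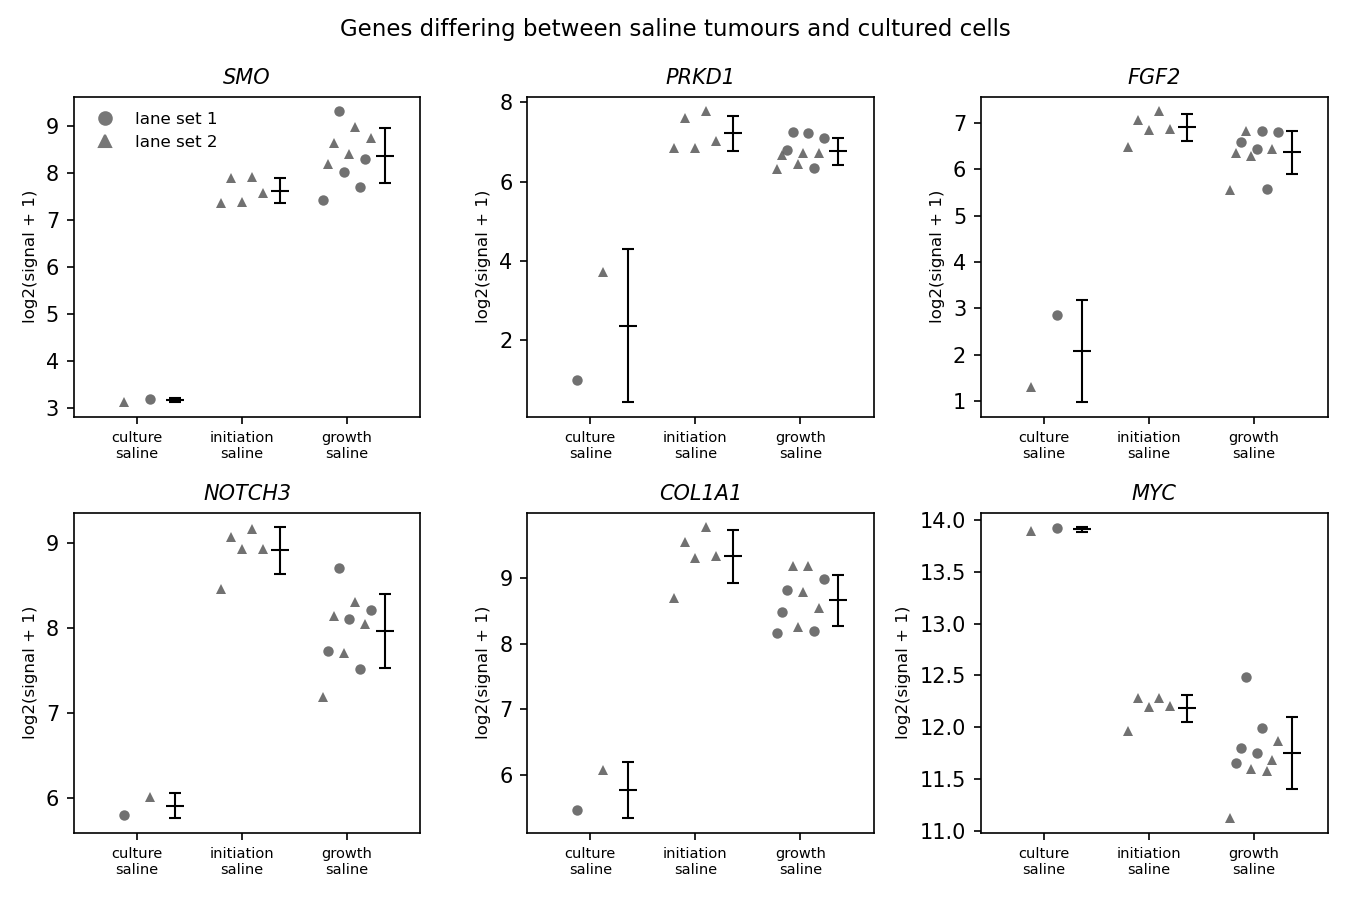
Log2 of signal plus 1 per lane for genes that differed between tumours and culture, in culture, initiation and growth saline lanes. Circles are lanes of set 1, triangles lanes of set 2, and black bars mean ± SD on that log2 scale. Unlogged SMO signal averaged 8.03 in culture, 200 in initiation and 354 in growth tumours, while that of MYC averaged 15404, 4668 and 3540.

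Growth and initiation saline tumours were compared as stages. The genes with the largest differences included CD8B, which had a mean signal of 144 ± 82.1 (SD, n = 10) in growth and 1.41 ± 0.516 (SD, n = 5) in initiation tumours. DLL3, a Notch ligand of neuroendocrine cells, had 188 ± 116 against 5.54 ± 3.81, and MYOD1, the muscle determination factor, 163 ± 91.5 against 7.30 ± 5.37. NANOG had 568 ± 243 against 101 ± 15.3. NOTCH3 was lower in growth tumours, at 259 ± 76.9 against 486 ± 85.2.

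limma called 46 genes higher and 5 lower in growth tumours, of 193, and 41 of the 51 were low-level genes in culture. The changes were +4.35 ± 0.56 SE for MYOD1 (adjusted p = 1.18e-07), +3.96 ± 0.47 for the chemokine gene CXCL12 (3.16e-08) and +2.35 ± 0.46 for NANOG (9.54e-05), each above every initiation tumour in 10 of 10. WNT10B had +4.20 ± 0.45 (5.41e-09). DLL3, under the floor of 4.99 in most initiation lanes, was at least 33.8-fold higher (5.41e-09). Against that floor, under which their initiation means lay, CD8B was at least 28.9-fold higher (1.03e-12) and COL2A1 at least 17.7-fold (1.93e-10), all 3 also in 10 of 10, and WNT8A, ASCL2, PDX1 and GAS1 were at least 10.8-fold to 18.1-fold higher. The 5 lower genes included ALDH2, a mitochondrial aldehyde dehydrogenase (−1.02 ± 0.35, 0.0276), CSNK1G2 (−0.96), NOTCH3 (−0.95 ± 0.28, 0.011) and the corepressor CTBP1 (−0.86); ALDH2 and NOTCH3 lay below the initiation mean in 10 of 10. ALDH2 also read 2003 in initiation SFN replicate 3, the lane with the least housekeeping signal (other SFN lanes 508 to 917). It read 1904 in growth SFN replicate 8, at a housekeeping signal of 9487, and the source of its signal was not tested. fry called 9 of 16 lists. Among them, 5 of 6 mesoderm and endoderm genes rose (fry adjusted p = 1.32e-07; adjusted p = 0.405 with an estimated correlation), as did 3 of 4 lymphoid and myeloid markers (3.03e-08; 0.405 likewise), 4 of 6 stroma markers (7.59e-06; 0.801 likewise) and 6 of 9 pluripotency genes (0.000391; 0.811 likewise). All initiation lanes with signal belong to set 2. Within that set 109 genes differed (60 higher, 49 lower), including all 51. The positive-control ratio of its growth saline lanes (2.35 to 2.44) did not overlap that of its initiation saline lanes (2.45 to 2.74). The fit within set 2 therefore cannot separate stage from a possible difference of assay run. Stage, day of removal, handling of each group and any difference of assay run cannot be told apart in this design.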

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

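The tests of scaling, of the set of lanes, of lane-wide signal, of RNA input and of stem-cell genes outside the study's list were chosen after the result was seen; the stroma tests, the study-list test and the splits were set down before their results were seen.

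A lane is listed when the highest or lowest lay far from its group, by a rule that picks out about 1 in 20 groups by chance. In initiation SFN replicate 3 the housekeeping geometric mean was 768 (others 10816 to 11583), the median low-level signal 1 (others 7.29 to 10.3) and the median abundant signal 57.3 (others 2674 to 2868). In initiation saline replicate 2 the positive controls had a geometric mean of 1 (others 535 to 848) and the low-level genes a median of 571 (others 6.99 to 11.9). Of 312 tests on 78 named genes, 68 stood apart. Initiation SFN replicate 3 was lowest for 37 genes and highest for 2, growth SFN replicate 3 lowest for 11, growth saline replicate 6 lowest for 4 and growth SFN replicate 1 lowest for 3. Initiation saline replicate 6 and initiation SFN replicate 5 were each highest for 3, initiation saline replicate 4 lowest for 2, growth saline replicate 2 lowest for 1, and growth saline replicate 4 and initiation saline replicate 3 each highest for 1.

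Low-level genes were higher in growth tumours: 50 of 53 had a higher value than in culture, with a median log2 difference of 3.43 (3.11 with signals raised to the negative-control floor) against −0.56 for abundant genes. The set of lanes is argued against, since the smaller of the within-set medians was 3.18. Scaling to the housekeeping genes gave a median of 3.81. Their signal was already lower in growth than in culture saline lanes (means 8718 and 10879), so scaling could only raise the median. Less RNA lowers signal and could not have produced the rise, so the scaling decides nothing about it. Mouse tissue read by the human probes stays open: the stroma list's median of 2.85 stood at percentile 47.6 of random lists matched on level, but host RNA behind the whole rise would raise those lists too, so the bound set for this test was wrong and it excludes nothing. The genes moved together from tumour to tumour (mean correlation within growth groups 0.634 over gene pairs, which are not independent). A background of these lanes not removed by the controls, and tumour stage itself, also remain open and may each account for it.

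Low-level genes were lower with SFN in growth tumours. A lane-wide shift goes with the values: 12 low-level markers of other lineages had a median of −0.90, as low as the −0.69 of 9 stem-cell members. RNA input stays open, since low-level minus abundant genes differed by −0.37 (permutation p = 0.379, adjusted p = 0.380; within set 1 +0.20, exact permutation p = 0.770, adjusted p = 0.770; within set 2 −0.94, exact permutation p = 0.0238, adjusted p = 0.0952), while without growth SFN replicate 1 the abundant median moved from −0.29 to −0.10 and the low-level one remained −0.72; scaled to the housekeeping genes they were −0.09 and −0.52. Within growth groups the mean correlation of low-level with abundant genes was −0.153, against 0.634 among pairs of low-level genes. Differing RNA input would move both classes together. These values argue against it as the main source of low-level variation within a treatment, but do not settle the SFN difference. The study's list lay at percentile 0 of matched lists. That decides nothing, because the list is taken to have been chosen on these samples. The 12 stem-cell genes outside it lay at percentile 9.35 (median −0.54). A fall confined to stem-cell genes is therefore not shown, and could not be separated from a lane-wide one.

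Genes higher in initiation tumours than in culture had a median of 3.00 over 11 genes (3.02 with signals raised to the floor). A lane-wide rise is argued against, since all 53 low-level genes had a median of 0.45. The 46 not called had 0.36 (0.050 with signals raised to the floor), a value partly set by leaving out the called genes. After scaling to the housekeeping genes the 11 had 3.23. Housekeeping signal was already lower in initiation than in culture saline lanes (means 9466 and 10879). Scaling could therefore only raise the median, and decides nothing about less RNA. Mouse tissue read by the human probes stays open: the stroma list stood at percentile 0.21 (median −0.73), with COL1A1 called higher (+3.56) and COL2A1 called lower, but in initiation SFN replicate 3, almost without human housekeeping signal, PRKCB read 2118 (other SFN lanes 134 to 189), CDH2 202 (53.6 to 80.2), WNT11 160 (51.2 to 87.8), PRKD1 191 (74.8 to 128) and SMO 175 (110 to 159). COL1A1 read 4.22 there (475 to 658) and FGF2 48.4 (79.6 to 124). Growth SFN replicates 1 and 2, with the least housekeeping signal of their group (3076 and 4717), read 1139 and 737 for PRKCB (other SFN lanes 91.6 to 335). For CDH2 they read 354 and 146 (46.3 to 95.8). WNT11 (177) and PRKD1 (185) were highest in replicate 1 but not high in replicate 2 (88.4 and 114). SMO read 290 and 243 there, below replicates 8 and 9 (366 and 361). Growth saline replicate 6, at a housekeeping signal of 4847, read 130 for PRKCB and 65.1 for CDH2, within the range of the other saline lanes. A non-tumour source may account for some of the 11 genes, without a test that decides it. A difference of assay run also stays open, since no culture saline lane shared the positive-control range of the initiation saline lanes.

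Of the calls in both culture comparisons, 10 genes were higher in both and 1 lower, where independent lists would share 3.19 and 0.0415. Simulated groups without changed genes, with independent noise and the same culture lanes, shared 0.03 on average in 100 simulations. Few genes are called in such data, so that value does not measure the effect of shared lanes on real calls. The 2 shared culture lanes add to such an overlap, by an amount that was not measured.

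Other splits of the lanes, 100 per result, bear on chance. For the stage difference chance is argued against: 51 genes against at most 39 in any other split drawn. Thus 1 of 100 was as large, the real one itself, which is the smallest share that 100 splits can give. For SFN in growth, in initiation and between stages, and for the lists of growth and initiation, the real count was 0, so all 100 splits were as large by construction and nothing about chance follows. The highest other was 0 for each, though another random draw for SFN in growth held a split that called genes. Without initiation SFN replicate 3, 5 of 100 splits gave at least the real 22 lower genes in growth tumours, the highest 94, so chance is not excluded. That other draw of 100 splits, made before a further test was added, put this share under 0.05, so it lies close to that line and the draw decides the side. A split with several times the real count points to a structure among the growth lanes; the split along the sets of lanes called 0 genes.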

How the results depend on the processing

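Leaving out weak lanes or genes under 32, the lane-set fits and keeping the lane without signal were chosen after seeing the data. No named gene changed direction where it was called in either setting. Signs of uncalled values did change, in 14 of 22 named genes for SFN in initiation tumours, 7 of 21 in growth tumours, 7 of 23 in culture, 3 of 37 for growth against initiation, 1 of 40 for growth against culture and 5 of 10 for the stage difference of the SFN effect. Unless said otherwise, the cause was not tested.

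SFN in growth tumours (0 genes) gave 8 with pseudocount 10, 33 with array weights, 3 with only both groups fitted, 28 by the series' rule, 32 by that rule with the unequal-variance test, 22 without the weak initiation lane, 10 without weak lanes, 19 with the set of lanes as a covariate and 47 in set 2 alone; leaving out 1 lane gave 0 to 9 (9 without growth saline replicate 2). It stayed at 0 in both scalings. Its lists (0) gave 6 with camera at the preset correlation, 11 without the weak initiation lane and 11 with the set covariate; leaving out 1 lane gave 0 to 3.

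SFN in initiation tumours (0) gave 1 with array weights, 3 by the series' rule, 1 by that rule with the unequal-variance test and 2 without the weak lane and scaled to housekeeping; leaving out 1 lane gave 0 to 0. The stage difference of the SFN effect (0) gave 18 with array weights and 2 by the series' rule, and 0 to 0 by leaving out 1 lane, though genes at an unadjusted p under 0.05 went from 2 to 30 without initiation SFN replicate 3. SFN in culture (0) gave 1 with trend and robust variance, 9 by the series' rule, 5 by that rule with the unequal-variance test and 14 with the set covariate; leaving out 1 lane gave 0 to 2 (2 without saline replicate 1), where the lone lane is assumed to vary like the others. Its lists (0) gave 5 scaled to housekeeping. Lists gave 0 to 0 by leaving out 1 lane in initiation and in culture.

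Growth against initiation saline (51) gave 77 centred on the median gene (58 higher, 19 lower), 145 with array weights, 82 with only both groups, 78 by the unequal-variance test at the series' rule and 95 adjusted, 88 without weak lanes, 107 without the weak lane and scaled to housekeeping, and 109 in set 2 alone; leaving out 1 lane gave 46 to 54. With the lane without signal kept it was 36, growth against culture 47, initiation against culture 11, and each SFN result in tumours 0.

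Growth against culture (60) gave 93 in either scaling, 154 with array weights, 102 by the unequal-variance test at the series' rule and 110 adjusted, 98 without the weak initiation lane, 115 without weak lanes, 124 without the weak lane and scaled, 94 with the set covariate and 5 among genes of at least 32; leaving out 1 lane gave 45 to 64. Initiation against culture (13) gave 30 scaled to housekeeping (21 higher, 9 lower, 8 shared), 41 centred, 112 with array weights, 76 with only both groups, 27 by the series' rule, 59 by that rule with the unequal-variance test and 45 adjusted, 39 without the weak initiation lane, 55 without weak lanes, 80 without the weak lane and scaled, and 5 among genes of at least 32; leaving out 1 lane gave 5 to 13 (5 without culture saline replicate 1).

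The replicate numbers showed no pairing of the growth lanes: within-number r ran from −0.82 to 0.74 over 10 pairs, and the own number matched best in 1. In initiation tumours r ran from −0.26 to 0.33 over 5 pairs, and the own number matched best in 3. Pairing is therefore neither shown nor excluded for initiation tumours. In culture both pairs had 0.33, and the number there is also the lane set, so pairing and set cannot be told apart. With the replicate number as a block, growth SFN gave 9 genes and 1 list, culture SFN 14, growth against culture 0, and growth against initiation 62; initiation against culture gave no such fit. Low-level genes sit near the negative-control floor of 4.99 in culture, which limits their folds.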

Other observations

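The setting without initiation SFN replicate 3 and the genes named in this part were chosen after the result was seen. In growth tumours without initiation SFN replicate 3, the genes that passed as lower with SFN included ABCG2, a drug-efflux transporter (mean signal 123 ± 46.2 with saline and 70.02 ± 25.1 with SFN, n = 10 each; below the saline mean in 10 of 10), and MAPK10, a stress-activated kinase of neurons (96.2 ± 35.6 and 48.9 ± 16.1; 10 of 10). With all tumours their limma adjusted p-values were 0.279 and 0.248. In culture the ABCG2 signal was 34.0 with saline and 57.9 with SFN, the opposite direction (adjusted p = 0.311, 2 of 2 lanes); the difference between culture and tumours was not tested.

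The T-box gene T, also named TBXT and a marker of early mesoderm, had a mean signal of 137 ± 77.1 (n = 10) in growth and 10.01 ± 5.01 (n = 5) in initiation saline tumours (limma adjusted p = 1.65e-06, above every initiation tumour in 10 of 10). CD3D, part of the T-cell receptor complex, had 89.4 ± 53.7 and 9.14 ± 4.55 (4.63e-06; 10 of 10).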
